A study of Homo sapiens with 38 samples.

How the data were processed

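The deposited table holds expected counts per small RNA feature, which the authors made and did not scale between libraries. The submitters' processing notes list cutadapt 4.5, FastQC 0.12.1 and Bowtie 1.3.1 with the genome build GRCh38.p13, and do not name the counting tool or the annotation. Reads that match several features appear divided among them: 6.71% of the values are not whole (tolerance 1e-06). They were rounded before the tests. Entries that share reads with copies, such as Y RNA, snRNA and 7SL RNA pseudogenes or tRNA isodecoders, are uncertain as single features. The table has 22549 features in 38 libraries and gives the RNA classes and coordinates used. Libraries were named by group and replicate letter. The labels state separate medium pools: 3 of 1360 mL, 48 h serum-free, for 2D and 4 of 400 mL, no time given, for 3D. These confound cultures. Letters are not tied to pools, which 3D methods may share, so p-values measure only the spread between these libraries. The table's name holds 2 project numbers, so 2 batches of unknown membership may confound cultures and methods.

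The groups, comparisons, tests, filters, feature lists and the rule for named features were set before the data were examined, except where stated. Differences between groups were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, robust) with all 38 libraries in 1 fit of 11 group means and 27 residual degrees of freedom, TMM scaling and filterByExpr with a minimum count of 10, which kept 7009 features. The common biological coefficient of variation was 1.11. Features with a Benjamini-Hochberg adjusted p below 0.05 over the 7009 passed, with no limit on fold. The SE of a log2 fold change is its size divided by the root of the F statistic. Two-sided tests were used throughout.

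CPM and shares rest on library totals, while log2 fold changes rest on TMM, whose factors ran from 0.0551 to 13.5. A log2 fold change and the ratio of CPM can therefore differ, and counts by library totals are given beside the others. Medians over all features are medians of fitted values, in which a feature with 0 counts in a group has no firm size. For such a feature the fold is given as a bound, taken against 3 counts over the total of the group. Intervals and bounds cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Confidence intervals of shares are 95% Wilson intervals.

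The feature lists were let-7, miR-200, intestinal epithelial miRNAs, miR-17-92 and paralogs, miR-10 with miR-99, miR-100 and miR-125, colorectal oncomiRs, miR-23, miR-27, miR-24, miR-29 and miR-30, miRNA entries overlapping other structured RNAs, blood cell, endothelial and liver miRNAs, mesenchymal and muscle miRNAs, C14 cluster miRNAs, Y RNAs, vault RNAs, nuclear-encoded tRNAs, mitochondrial tRNAs, C/D box snoRNAs, H/ACA box snoRNAs, scaRNAs, spliceosomal snRNAs, 7SL RNA, 7SK RNA, cytosolic rRNAs, mitochondrial rRNAs and tRNAs reported as 5′-half fragments. They were written from textbook knowledge. Of the C14 cluster 15 members were in the table and 0 were tested, and 0 entries matched the mitochondrial rRNA list. The cytosolic rRNA pattern matched 5S and 5.8S copies (12 tested) and missed the 28S and 18S entries. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Where a camera adjusted p below 0.05 is printed alone, the call also held with the estimated correlation. Camera compares a list with the other features, so its direction can differ from the sign of a list's median. This was so for Y RNAs in 3D against 2D sEV (median -0.19, called up), for C/D box, H/ACA box, spliceosomal and miR-10 lists in 3D against 2D supermere (medians -1.18, -0.64, -0.48 and -0.42, called up), and for nuclear-encoded tRNAs in gradient 6_7 against sEV (-0.86, called up) and in the difference between cultures (-1.94, called up).

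Named features are the 5 largest positive and 5 largest negative log2 fold changes per comparison among those that passed, with a mean of at least 50 CPM in the higher group and ranges that do not overlap, 1 per family and direction. To these come 2 to 4 members of each list that passed, by highest mean CPM, and a fixed set of 16 features (hsa-miR-1246, hsa-miR-21-5p, hsa-miR-100-5p, hsa-miR-125b-5p, hsa-miR-10b-5p, hsa-let-7a-5p, hsa-miR-92a-3p, hsa-miR-200c-3p, hsa-miR-210-3p, hsa-miR-122-5p, hsa-miR-451a, RNY1, RNY3, RNY4, RNY5 and VTRNA1-1), of which RNY5 was not found in the table. 28S rRNA is one of the largest changes, and no feature outside the rule is named.

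RNA class shares were compared with exact permutation tests over all assignments, two-sided, on the sum of squares between groups, adjusted over classes. With 3 against 3 libraries no such test can fall below 0.10, so 3 fractions were tested jointly or cultures stratified by fraction. Replicate letters were checked as a pairing: the residual correlation was above 0.1 in every pair, where there were 3 or more pairs, only for 2D UC supermere with exomere (0.568 to 0.854) and for exomere in 3D with 2D (0.114 to 0.377). Other settings were RLE scaling, library totals, no filter, a filter of 10 CPM in 3 libraries, the compared groups fitted alone, DESeq2 1.42.0, a block for the letter, each library left out and miRNA features alone. Leaving out the near-empty library, also with RLE or library totals, and summing copies of a family were added after the data were seen.

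Simulated data had 200 changed features of 10 to 1000 CPM. The test recovered 0 to 14% of 4-fold changes, 36 to 80% of 16-fold and 84 to 100% of 64-fold, with 0.935 to 4.10% of calls false. With changed features of 10 CPM or more, recovery was 26 to 90% at 16-fold and 58 to 98% at 64-fold. False calls reached 19.6% in gradient 12 against 6_7 and 8.51% in supermere against sEV in 3D. Camera called an unchanged list in both, so list results there can follow a shift in composition. Rates may differ where most changes go 1 way, as often here. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.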

Results

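Small RNA was sequenced from material that DiFi cells, a human colorectal cancer line, release into the medium. The RNA was first treated with AlkB, an enzyme that removes base methylations that stop reverse transcription, so that tRNA and other modified RNAs could be read. Small extracellular vesicles (sEV), exomeres and supermeres, the last 2 being small non-vesicular particles, were pelleted by ultracentrifugation (UC) from flat culture (2D) or from a hollow-fibre bioreactor (3D), with 3 libraries for each fraction and culture. Exomeres and supermeres of the 3D medium were also isolated by size-exclusion chromatography (FPLC), with 4 libraries each. A cushion density gradient of the 3D medium gave pools of fractions 6_7, 9_10 and 12, with 4 libraries each. The gradient labels name light vesicles, heavy vesicles and non-vesicular material without tying each to a fraction, so the pools keep their fraction numbers. The 11 groups hold 38 libraries. Total counts per library ran from 10751387 to 16991360 in 2D UC sEV, 5443716 to 13171570 in 2D UC exomere and 4678081 to 11645739 in 2D UC supermere. In 3D UC they were 2889572 to 4146361 for sEV and 3380807 to 15344549 for exomere, and 3558019 to 4656610 and 1478602 to 12958289 for FPLC exomere and supermere. The gradient pools were shallower, with 940808 to 3860718 in 6_7, 81079 to 490374 in 9_10 and 1024324 to 1985349 in 12. The 3D UC supermere libraries ran from 46 to 4137859 counts, and replicate A, with 46, was close to empty. Of its counts 31 were Y RNA, 67.4% with a 95% Wilson interval of 53.0 to 79.1%. Its shares and counts scaled to library totals (CPM, 1e6 counts per library) are left out of the 3D UC supermere means, which rest on 2 libraries, while the fits and the permutation tests of shares keep it.

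The RNA classes differed between fractions and between cultures. Y RNAs, small RNAs that bind the Ro60 protein, made up 75.3% ± 8.73 (SD, n = 3) of the counts in 3D UC exomere and 87.0% ± 9.31 (SD, n = 2) in 3D UC supermere, against 20.4% ± 6.11 (SD, n = 3) in 3D UC sEV. In 2D UC the Y RNA share was 9.33% ± 0.449 in exomere, 4.53% ± 0.378 in supermere and 13.2% ± 1.2 in sEV (SD, n = 3 each). tRNA took 20.7% ± 1.62 of 2D UC sEV counts and 0.625% ± 0.159 and 0.296% ± 0.0856 of 2D UC exomere and supermere counts. miRNAs were on average the largest class in the fractions of 2D UC, at 52.0% ± 3.83, 63.1% ± 5.31 and 53.6% ± 13.9 for sEV, exomere and supermere, though supermere C held 52.0% snRNA and 37.5% miRNA. Across the 3 fractions of 2D UC, the Y RNA, tRNA and miscellaneous RNA shares differed (exact permutation test, two-sided, adjusted p = 0.0119 each), as did rRNA, snRNA and snoRNA (adjusted p = 0.0298), while miRNA did not (adjusted p = 0.425). Across the fractions of 3D UC the miRNA and miscellaneous RNA shares differed (adjusted p = 0.0179), and Y RNA, rRNA and snoRNA had adjusted p = 0.0714; without the near-empty library rRNA (adjusted p = 0.0179) and Y RNA (adjusted p = 0.0357) passed and miscellaneous RNA did not (adjusted p = 0.0714). Between cultures, stratified by fraction (8000 assignments), miRNA (adjusted p = 0.00125), endogenous retrovirus RNA (adjusted p = 0.00125), Y RNA (adjusted p = 0.00250), miscellaneous RNA (adjusted p = 0.0112) and lncRNA (adjusted p = 0.0345) differed.

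rRNA took a large share of the counts in the FPLC preparations and in gradient pool 12. FPLC exomere had 26.2% ± 11.6 rRNA, 25.3% ± 15.8 miRNA and 21.0% ± 2.55 Y RNA, and FPLC supermere had 56.8% ± 35.0 rRNA, with single libraries between 7.67 and 90.6%, and 23.3% ± 10.2 Y RNA (SD, n = 4). The Y RNA share differed between FPLC and 3D UC, stratified by fraction (exact permutation test, two-sided, adjusted p = 0.00816), and so did rRNA (adjusted p = 0.0490). Between FPLC supermere and exomere the tRNA, snoRNA, mitochondrial tRNA, lncRNA, miscellaneous RNA and endogenous retrovirus RNA shares differed (adjusted p = 0.0476 over 70 assignments), but none of these 6 passed without FPLC supermere A, B, C or D, and rRNA had adjusted p = 0.179. In the gradient, pool 12 held 53.8% ± 13.2 rRNA and 0.291% ± 0.0803 Y RNA, pool 6_7 25.9% ± 21.4, with 55.9% in B and 7.92 to 26.3% in the others, and 3.62% ± 1.42, and pool 9_10 7.07% ± 3.30 and 11.2% ± 5.96 (SD, n = 4 each). tRNA took 23.1% ± 9.04 in 6_7, 20.9% ± 6.18 in 9_10 and 0.502% ± 0.387 in 12. lncRNA, endogenous retrovirus RNA, tRNA, rRNA, Y RNA and snRNA (adjusted p = 0.00173, 0.0104, 0.0144, 0.0211, 0.0233 and 0.0249) differed between the pools, and miRNA had adjusted p = 0.494.

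**Figure D1:**
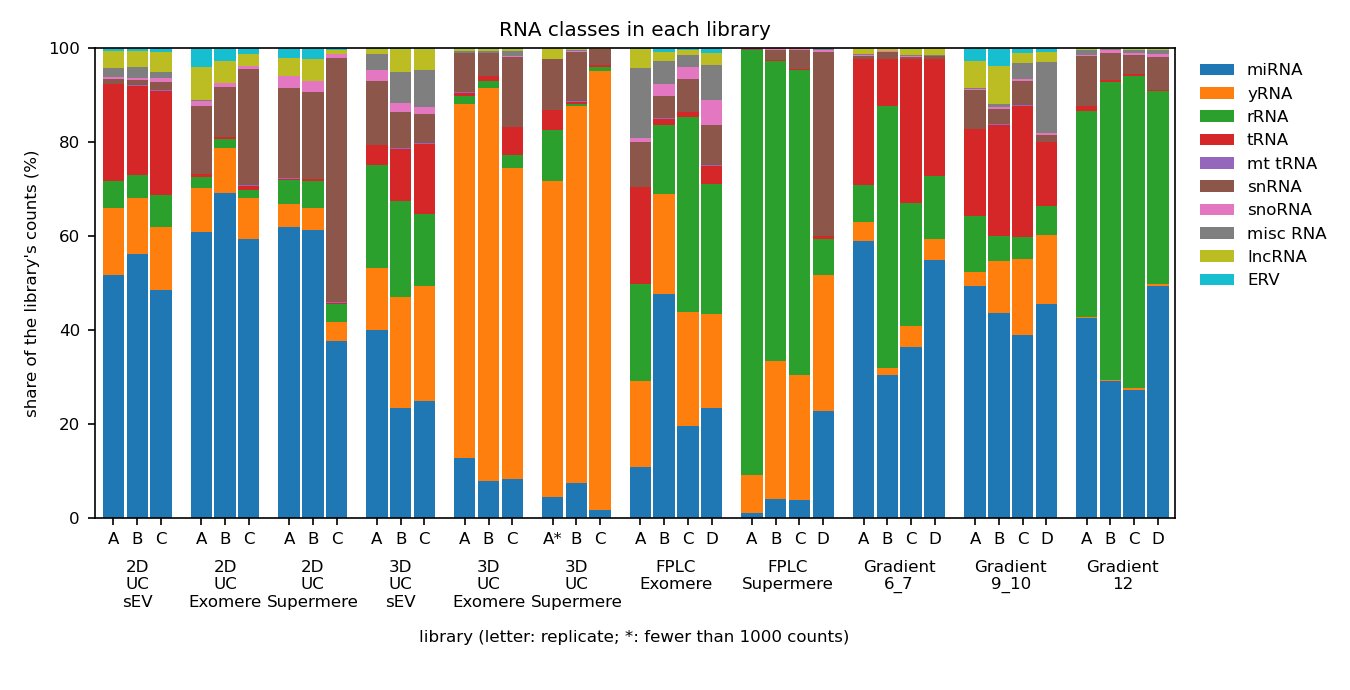
Stacked bars of the percent of counts in each RNA class, 1 bar per library, grouped by culture, isolation and fraction; the bar with a star is the library with 46 counts. Y RNA fills most of the 3D UC exomere and supermere bars, 66.4 to 83.9% in the exomere, and rRNA most of 3 of the 4 FPLC supermere bars.

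In 3D culture, supermeres held less vault RNA, let-7 and miR-200 miRNA and snoRNA than sEV. The vault RNAs, the RNAs of the large cytoplasmic vault particle, fell: VTRNA1-1 (chromosome 5, 140711275 to 140711373) was at 3.02 ± 3.93 against 46160 ± 18189.6 CPM (SD, n = 2 and 3 in supermere against sEV, log2 fold change -13.94, SE 1.55, adjusted p = 2.5e-13), and VTRNA1-2 had 0 counts in supermere, at least 22449-fold below sEV. hsa-miR-200c-3p (chromosome 12, 6963742 to 6963764), which keeps cells epithelial, was at 4.95 ± 4.61 against 5692 ± 814 CPM (log2 fold change -10.06, SE 1.35, adjusted p = 1.3e-10), and hsa-let-7a-5p, of the growth-restraining let-7 family, at 53.4 ± 45.4 against 7272 ± 2833 CPM (log2 -7.00). hsa-miR-21-5p (chromosome 17, 59841273 to 59841294), an oncogenic miRNA, was at 837 ± 1004 against 46967 ± 13746 CPM (log2 -6.07). RNY1 (chromosome 7, 148987136 to 148987248) rose to 486388 ± 46699.7 against 91047 ± 8434 CPM (log2 fold change 2.42, SE 0.75, adjusted p = 0.0210), a member of the Y RNAs, of which 24 of 277 rose and 78 fell (55 and 108 adjusted over the list alone, camera adjusted p = 0.898). In the let-7 family 9 of 9 fell (9 adjusted over the list alone, camera adjusted p = 1.3e-15). The miR-200 family behaved alike, where 5 of 5 fell (5 adjusted over the list alone, camera adjusted p = 1.5e-12). Among the C/D box snoRNAs, which guide 2′-O-methylation, 85 of 152 fell (123 adjusted over the list alone, camera adjusted p = 4.0e-27), with SNORD3A, the U3 RNA of pre-rRNA processing, at 3.26 against 1373 CPM (log2 -8.19). For the H/ACA box snoRNAs, guides of pseudouridylation, 48 of 89 fell (74 adjusted over the list alone, camera adjusted p = 2.4e-20). Of the vault RNAs 4 of 4 fell (4 adjusted over the list alone, camera adjusted p = 1.0e-08). RNY4 (81115 against 24039.6 CPM, log2 fold change 1.78, adjusted p = 0.151) and hsa-miR-92a-3p (4753 against 7679 CPM, log2 fold change -0.73, adjusted p = 0.560) did not pass. In total 545 of 7009 features passed, 31 higher and 514 lower, and with library totals 391 passed, 6 higher and 385 lower, and the median log2 fold change of all features was -3.90 (-3.10 with library totals). Without 3D UC supermere B 207 features passed, and without supermere C 164. RNY1 lost its call without supermere C (log2 1.24) or any 1 sEV library (2.39 to 2.47). With RLE factors and without the near-empty library 296 passed, 156 higher and 140 lower, the Y RNA median being 0.34 there.

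Exomeres of 3D culture fell below sEV in snoRNA, hsa-miR-21-5p and hsa-miR-200c-3p. hsa-miR-92a-3p (chromosome 13, 91351361 to 91351382), of the growth-promoting miR-17-92 cluster, rose to 32945 ± 7594 against 7679 ± 1760.3 CPM (SD, n = 3 and 3) in exomere against sEV (log2 fold change 2.23, SE 0.79, adjusted p = 0.0463). RNY4 rose to 126508 ± 14299 against 24039.6 ± 11858 CPM (log2 fold change 2.60, SE 0.78, adjusted p = 0.0124). hsa-miR-21-5p fell to 1612 ± 968 against 46967 ± 13746 CPM (log2 -4.71), hsa-miR-200c-3p to 277 ± 69.3 against 5692 ± 814 CPM (log2 -4.26) and VTRNA1-1 to 3595 ± 2610.2 against 46160 ± 18189.6 CPM (log2 -3.65). hsa-miR-4497, an entry that overlaps rRNA sequence, had 0 counts in exomere and was at least 1115-fold lower. Of the C/D box snoRNAs 105 of 152 fell (123 adjusted over the list alone, camera adjusted p = 5.5e-39), and SNORD3A was at 32.6 against 1373 CPM (log2 -5.37). Of the H/ACA box snoRNAs 64 of 89 fell (73 adjusted over the list alone, camera adjusted p = 4.7e-28). In the miR-17-92 cluster and its paralogs 1 of 12 rose and 9 fell (1 and 9 adjusted over the list alone, camera adjusted p = 2.5e-05, adjusted p = 0.25 with an estimated correlation); hsa-miR-93-5p, a paralog, was at 54.2 against 2006 CPM (log2 -5.01). RNY1 (198685 against 91047 CPM, log2 fold change 1.32, adjusted p = 0.234) did not pass. For this pair 705 of 7009 features passed, 19 higher and 686 lower, and with library totals 514 passed, 14 higher and 500 lower, with a median log2 fold change over all features of -0.43 (-0.60 with library totals). Without 3D UC exomere B or C, 413 and 419 passed. hsa-miR-92a-3p lost its call without any 1 of the 6 libraries (log2 2.07 to 2.42) and RNY4 without exomere B or sEV A (2.22). RLE factors without the near-empty library gave 99 higher and 187 lower, the 2 groups alone 195 and 348, and miRNA alone 84 and 114.

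Supermeres and exomeres of 3D culture differed in few features by edgeR, among them the vault RNAs. VTRNA1-1 fell to 3.02 ± 3.93 against 3595 ± 2610.2 CPM (SD, n = 2 and 3) in supermere against exomere (log2 fold change -10.28, SE 1.44, adjusted p = 4.7e-08), and VTRNA1-2 had 0 counts in supermere, at least 3481-fold lower than in exomere. hsa-miR-200c-3p was at 4.95 ± 4.61 against 277 ± 69.3 CPM (log2 fold change -5.80, SE 1.16, adjusted p = 4.7e-04). RNU5E-1, a U5 snRNA of the spliceosome, rose to 2301 ± 766 against 80.5 ± 52.8 CPM (log2 4.89). Of the vault RNAs 4 of 4 fell (4 adjusted over the list alone, camera adjusted p = 3.5e-09, adjusted p = 0.0530 with an estimated correlation). Of the miR-200 family 2 of 5 fell (4 adjusted over the list alone, camera adjusted p = 4.4e-07, adjusted p = 0.106 with an estimated correlation). The tRNAs reported to be cut into 5′-half fragments included tRNA-Glu-TTC at 40.4 against 2449.8 CPM (log2 -4.88), and 1 of 9 fell (7 adjusted over the list alone, camera adjusted p = 4.0e-08, adjusted p = 0.117 with an estimated correlation). RNY1 was at 486388 against 198685 CPM (log2 fold change 1.10, adjusted p = 0.433) and hsa-miR-92a-3p at 4753 against 32945 CPM (log2 fold change -2.96, adjusted p = 0.0575), and neither passed. Between these fractions 26 of 7009 features passed, 9 higher and 17 lower, and with library totals 20 passed, 3 higher and 17 lower, and the median was -1.07 (-1.11 with library totals). Without 3D UC exomere A or B 17 and 15 passed, and without supermere B or C 13 and 8. Calls were lost for hsa-miR-200c-3p without supermere C (log2 -5.35), for VTRNA1-2 without supermere B or C, and for tRNA-Glu-TTC without exomere C or supermere B (-3.33 and -3.99). With RLE factors and without the near-empty library 58 passed, 45 higher and 13 lower. DESeq2 called 375, 347 higher and 28 lower, and within miRNA alone 82 passed, 7 higher and 75 lower.

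In flat culture, supermeres fell below sEV in VTRNA1-1, tRNA, hsa-let-7a-5p and hsa-miR-200c-3p. RNU11 (chromosome 1, 28648600 to 28648733), of the minor spliceosome, rose to 38329.7 ± 50192 against 223 ± 101 CPM (SD, n = 3 and 3, log2 fold change 7.96, SE 2.05, adjusted p = 0.00774), and RNU2-1, a U2 snRNA of the major spliceosome, to 100028 against 3048 CPM (log2 5.23). hsa-miR-1290, an entry that overlaps snRNA sequence, rose to 89.8 ± 82.2 against 1.86 ± 1.21 CPM (log2 6.02). VTRNA1-1 fell to 2.84 ± 1.00 against 13464 ± 3330.4 CPM (log2 fold change -12.50, SE 1.31, adjusted p = 4.3e-15) and tRNA-Gly-GCC, a common source of 5′-half fragments, to 259 against 107629 CPM (log2 -9.36). hsa-miR-200c-3p was at 47.3 ± 24.1 against 11249 ± 2698 CPM (log2 -8.78), hsa-let-7a-5p at 469 ± 281 against 20648 ± 3020.1 CPM (log2 -6.58) and RNY4 at 1362 ± 267 against 19200 ± 1252 CPM (log2 -4.37). Spliceosomal snRNAs went both ways, as 61 of 259 rose and 36 fell (84 and 41 adjusted over the list alone, camera adjusted p = 0.134). Of the Y RNAs 23 of 277 rose and 152 fell (35 and 164 adjusted over the list alone, camera adjusted p = 2.0e-45). For the intestinal epithelial miRNAs 4 of 7 fell (7 adjusted over the list alone, camera adjusted p = 6.8e-07), with hsa-miR-192-5p at 2875 against 27766 CPM (log2 -3.61) and hsa-miR-194-5p at 109 against 26659.7 CPM (log2 -8.14). Of the 5′-half tRNAs 8 of 9 fell (8 adjusted over the list alone, camera adjusted p = 1.9e-12). In the C/D box list 5 of 152 rose and 103 fell (7 and 118 adjusted over the list alone, camera adjusted p = 2.4e-34). For this pair 727 of 7009 features passed, 135 higher and 592 lower, and with library totals 575 passed, 138 higher and 437 lower, with a median of -0.01 (1.12 with library totals). Within miRNA alone 142 rose and 134 fell, with let-7 and miR-200 medians of -3.63 and -4.96. Supermere C held 96284 CPM of RNU11; without it the mean was 9353 CPM, and RNU11 (log2 3.71) and hsa-miR-1290 (2.94) lost their calls, RNU2-1 keeping 2.82. RNU11 also lost it without sEV A or C (7.91 and 7.62).

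In flat culture, exomeres held less tRNA-Gly-GCC, Y RNA and VTRNA1-1 than sEV. tRNA-Gly-GCC (chromosome 1, 161443304 to 161443374, first of 28 loci) fell to 494 ± 192 against 107629 ± 12938 CPM (SD, n = 3 and 3) in exomere against sEV (log2 fold change -9.45, SE 1.07, adjusted p = 8.3e-15). hsa-miR-30b-5p was at 3.87 ± 2.73 against 819.6 ± 231 CPM (log2 -9.44), hsa-miR-200c-3p at 228 ± 45.4 against 11249 ± 2698 CPM (log2 -7.23) and VTRNA1-1 at 328 ± 141 against 13464 ± 3330.4 CPM (log2 -7.07). RNU2-1 rose to 47411 against 3048 CPM (log2 2.68). Of the Y RNAs 0 of 277 rose and 154 fell (5 and 165 adjusted over the list alone, camera adjusted p = 1.3e-63), RNY4 being at 7791 ± 732 against 19200 ± 1252 CPM (log2 -2.73). Of the let-7 family 7 of 9 fell (7 adjusted over the list alone, camera adjusted p = 6.2e-13). The 7SL RNAs, of the signal recognition particle, fell in part, as 17 of 63 fell (24 adjusted over the list alone, camera adjusted p = 2.0e-15), with RN7SL2 at 30.5 against 224 CPM (log2 -4.70). In the rRNA list, mostly 5S and 5.8S copies, 5 of 12 fell (7 adjusted over the list alone, camera adjusted p = 4.5e-12). Of the spliceosomal snRNAs 24 of 259 rose and 11 fell (28 and 11 adjusted over the list alone, camera adjusted p = 0.848). There 601 of 7009 features passed, 44 higher and 557 lower, and with library totals 416 passed, 118 higher and 298 lower, with a median of 0.10 (1.79 with library totals). Without 2D UC exomere A or B, 375 and 384 passed. RNU2-1 lost its call without exomere C (log2 1.61) or sEV A or C (2.53 and 2.84) and RNY4 without exomere A or B (-2.06 and -2.20). RLE scaling gave 165 higher and 200 lower, and miRNA alone 132 and 111.

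Between supermere and exomere of flat culture the called features were few and lower in supermere. VTRNA1-1 was at 2.84 ± 1.00 against 328 ± 141 CPM (SD, n = 3 and 3, log2 fold change -5.43, SE 0.99, adjusted p = 6.5e-04), VTRNA1-3 at 0.0286 against 6.24 CPM (log2 -5.08) and VTRNA3-1P, a vault RNA pseudogene, at 0.0286 against 5.59 CPM (log2 -5.05). Of the vault RNAs 3 of 4 fell (4 adjusted over the list alone, camera adjusted p = 1.2e-09). SNORA62 ENSG00000202363.1 and SNORD57, both snoRNAs, had 0 counts in supermere, at least 63.3-fold and at least 37.3-fold lower. In the spliceosomal list 0 of 259 rose and 0 fell (19 and 14 adjusted over the list alone, camera adjusted p = 0.00475, adjusted p = 0.886 with an estimated correlation). With edgeR 6 of 7009 features passed, 0 higher and 6 lower, and with library totals 7 passed, 0 higher and 7 lower, and at an unadjusted p below 0.05 there were 300. The spliceosomal median turned to -0.02 with library totals. The median was -0.09 (-0.67 with library totals). Without 2D UC supermere A or B 0 features passed, 17 without exomere C and 29 without supermere C. VTRNA1-1 also lost its call without supermere C (log2 -6.86) or exomere A or B (-5.60 and -5.76).

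In sEV, snRNA and snoRNA features were higher in 3D than in 2D culture. RNU12, of the minor spliceosome, rose to 32035 against 748 CPM (n = 3 and 3, log2 6.53), and tRNA-Ile-TAT to 1169 ± 1107 against 24.0 ± 0.298 CPM (SD, n = 3 and 3) in 3D against 2D (log2 fold change 6.48, SE 1.79, adjusted p = 0.0360). hsa-miR-4497 rose to 109.8 ± 24.2 against 1.42 ± 1.05 CPM (log2 7.15) and hsa-miR-125b-5p, of the miR-10 and miR-125 group, to 160.0 ± 83.4 against 26.9 ± 4.26 CPM (log2 fold change 3.60, SE 1.00, adjusted p = 0.0167). hsa-miR-592 fell to 1.41 ± 0.951 against 115 ± 107 CPM (log2 fold change -5.20, SE 1.19, adjusted p = 0.00126). Of the spliceosomal snRNAs 55 of 259 rose (125 adjusted over the list alone, camera adjusted p = 1.1e-84). The H/ACA box snoRNAs rose in part, as 22 of 89 rose (40 adjusted over the list alone, camera adjusted p = 3.3e-40), with SNORA71A at 86.3 ± 31.4 against 2.70 ± 1.24 CPM (log2 5.98). For 7SK RNA, which holds back the elongation factor P-TEFb, and its copies 7 of 22 rose (10 adjusted over the list alone, camera adjusted p = 9.4e-13). Among the nuclear-encoded tRNAs 23 of 49 rose and 0 fell (30 and 1 adjusted over the list alone, camera adjusted p = 1.0e-15, adjusted p = 0.211 with an estimated correlation), including tRNA-iMet-CAT at 2924 against 117 CPM (log2 5.54). The tRNA share was 10.1% ± 5.47 in 3D against 20.7% ± 1.62 in 2D (SD). Of the miR-23, miR-29 and miR-30 group 3 of 13 rose (3 adjusted over the list alone, camera adjusted p = 0.00259, adjusted p = 0.455 with an estimated correlation), and its median was above 0 with TMM and below 0 with library totals. For this fraction 207 of 7009 features passed, 204 higher and 3 lower, and with library totals 58 passed, 51 higher and 7 lower, with a median of -0.77 (-1.70 with library totals). Without 2D UC sEV A, B or C, 70, 70 and 75 passed, and without 3D UC sEV B or C 118 each. RNU12 reached 83566 CPM in 3D UC sEV A; without it the mean was 6270 CPM and the log2 3.93, and its call was lost with library totals and without 2D sEV A or C (6.20 and 6.33). Without any 1 2D sEV library tRNA-Ile-TAT (6.32 to 6.50) and hsa-miR-125b-5p (3.31 to 3.57) lost theirs, the latter also without 3D sEV A (2.92). RLE factors without the near-empty library gave 48 higher and 48 lower, the 2 groups alone 533 and 230, and miRNA alone 32 and 28.

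In exomeres, Y RNA, vault RNA and tRNA features were higher and hsa-miR-21-5p was lower in 3D than in 2D culture. RNY4 (chromosome 7, 148963315 to 148963410) rose to 126508 ± 14299 against 7791 ± 732 CPM (SD, n = 3 and 3, log2 fold change 6.56, SE 0.93, adjusted p = 3.4e-09), RNY1 to 198685 ± 47722 against 50858 ± 5856 CPM (log2 4.65) and VTRNA1-1 to 3595 ± 2610.2 against 328 ± 141 CPM (log2 6.09). tRNA-Thr-TGT rose to 498 ± 75.2 against 13.6 ± 7.38 CPM (log2 7.66). hsa-miR-21-5p fell to 1612 ± 968 against 198970 ± 45223 CPM (log2 fold change -4.33, SE 0.85, adjusted p = 6.2e-05), hsa-miR-592 to 0.304 ± 0.527 against 544 ± 168 CPM (log2 -7.84), and hsa-miR-660-3p had 0 counts in 3D, at least 557-fold lower. hsa-miR-92a-3p was at 32945 ± 7594 against 10881 ± 1699 CPM (log2 4.07). Of the Y RNAs 134 of 277 rose (191 adjusted over the list alone, camera adjusted p = 1.1e-113). Of the nuclear-encoded tRNAs 34 of 49 rose (44 adjusted over the list alone, camera adjusted p = 4.2e-39). Of the 5′-half tRNAs 9 of 9 rose (9 adjusted over the list alone, camera adjusted p = 8.3e-14), and of the vault RNAs 4 of 4 rose (4 adjusted over the list alone, camera adjusted p = 2.2e-07). Colorectal oncomiRs split, as 3 of 12 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.00149, adjusted p = 0.237 with an estimated correlation). In the let-7 family 5 of 9 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 1.9e-04, adjusted p = 0.185 with an estimated correlation); hsa-let-7a-5p had a log2 of 2.45 with TMM at 468 against 631 CPM, and -0.44 with library totals, and hsa-miR-200c-3p had 2.93 with TMM and -0.69 with RLE scaling. In exomere 603 of 7009 features passed, 359 higher and 244 lower, and with library totals 3725 passed, 80 higher and 3645 lower, and the median was -1.26 (-4.03 with library totals); the medians of let-7, miR-200, colorectal oncomiRs and C/D box snoRNAs turned below 0 with library totals, while those of Y RNA, vault RNA and nuclear tRNA stayed above 0. Without 2D UC exomere A, B or C, 194, 199 and 383 passed, and without 3D UC exomere B or C 327 and 291. VTRNA1-1 lost its call without 2D exomere A (log2 6.06), hsa-let-7a-5p without any 1 of the 6 libraries (1.86 to 2.66) and hsa-miR-200c-3p without exomere A or B of either culture (2.56 to 2.76).

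**Figure D2:**
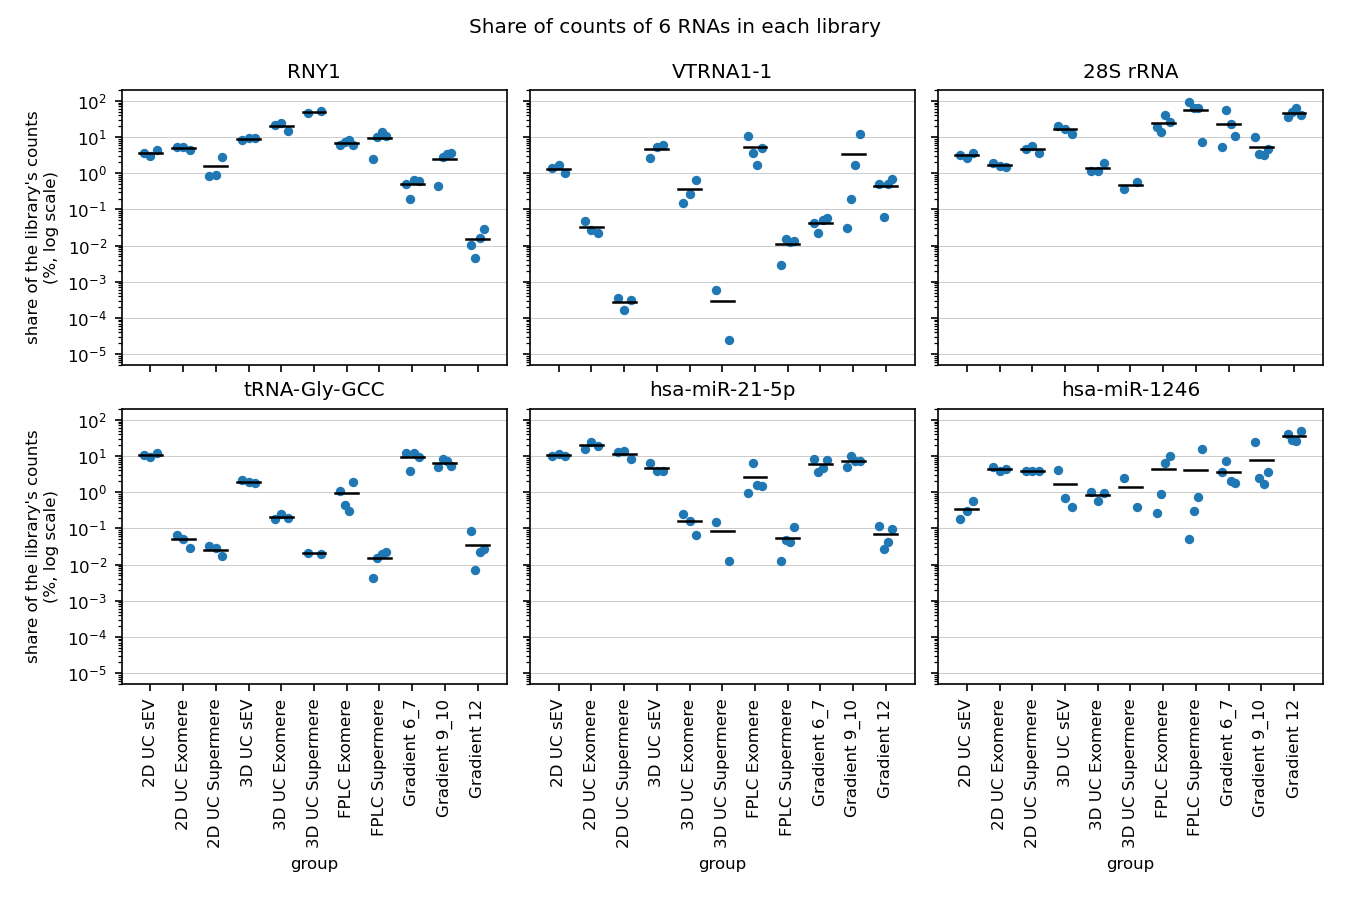
Percent of counts (log axis) per library for 6 RNAs, in the 11 groups; points are libraries, lines are group means, and the library with 46 counts is left out. VTRNA1-1 is lower in supermere than in exomere in 2D UC, 3D UC and FPLC.

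Supermeres changed with culture in the same direction for Y RNA. RNY1 rose to 486388 ± 46699.7 against 15412 ± 11710.2 CPM (SD, n = 2 and 3) in 3D against 2D (log2 fold change 5.67, SE 0.87, adjusted p = 5.2e-08), RNY4 to 81115 ± 4719 against 1362 ± 267 CPM (log2 7.38) and mt-tRNA18-TS2, a mitochondrial serine tRNA, to 883 ± 9.44 against 30.7 ± 12.6 CPM (log2 6.05). hsa-miR-21-5p fell to 837 ± 1004 against 116721 ± 30508 CPM (log2 fold change -5.77, SE 0.93, adjusted p = 4.3e-07), hsa-let-7b-5p to 79.7 against 5860.2 CPM (log2 -4.51) and RNU2-1 to 7234 against 100028 CPM (log2 -3.44). hsa-miR-592 and SNORD22 ENSG00000277194.1 had 0 counts in 3D, at least 237-fold and at least 174-fold lower. Of the Y RNAs 87 of 277 rose (111 adjusted over the list alone, camera adjusted p = 3.0e-108). Of the mitochondrial tRNAs 7 of 21 rose and 0 fell (9 and 3 adjusted over the list alone, camera adjusted p = 2.4e-11), their median turning to -0.12 with library totals. In the spliceosomal list 8 of 259 rose and 20 fell (12 and 46 adjusted over the list alone, camera adjusted p = 3.0e-07, adjusted p = 0.279 with an estimated correlation), camera calling it up against the other features although its median log2 was -0.48. In supermere 224 of 7009 features passed, 134 higher and 90 lower, and with library totals 1131 passed, 90 higher and 1041 lower, with a median of -4.68 (-5.84 with library totals). Without 3D UC supermere C 72 passed. Without it RNY1 had a log2 of 4.42 and RNY4 6.18, and hsa-let-7b-5p (-4.06) and RNU2-1 (-3.20) lost their calls, RNU2-1 also without 2D supermere C (-1.11).

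FPLC supermeres held less VTRNA1-1, miR-200 miRNA and snoRNA than FPLC exomeres. VTRNA1-1 was at 112 ± 56.5 against 53196 ± 39030.4 CPM (SD, n = 4 and 4, log2 fold change -6.15, SE 0.88, adjusted p = 1.8e-08), hsa-miR-200c-3p at 16.8 ± 12.6 against 4829 ± 4089 CPM (log2 -5.63) and hsa-miR-21-5p at 527 ± 403 against 26468 ± 26244 CPM (log2 -3.07). hsa-miR-18a-5p, of the miR-17-92 cluster, had 0 counts in supermere, at least 647-fold lower, and SNORD68, a C/D box snoRNA, fell to 0.0230 ± 0.0460 against 260.3 ± 233 CPM (log2 -9.84). RNY1 was at 92838 ± 49118 against 69332 ± 9923 CPM (log2 fold change 3.07, SE 0.67, adjusted p = 2.4e-04) and RNY4 at 26946 ± 12122 against 26188 ± 3644 CPM (log2 2.82, 0.04 with library totals). Of the Y RNAs 37 of 277 rose and 102 fell (71 and 113 adjusted over the list alone, camera adjusted p = 0.567), and their share was 23.3% ± 10.2 against 21.0% ± 2.55 (adjusted p = 0.825). Of the vault RNAs 4 of 4 fell (4 adjusted over the list alone, camera adjusted p = 2.3e-06, adjusted p = 0.0914 with an estimated correlation). Of the miR-200 family 5 of 5 fell (5 adjusted over the list alone, camera adjusted p = 8.5e-08, adjusted p = 0.0914 with an estimated correlation). For C/D box snoRNAs 6 of 152 rose and 56 fell (9 and 74 adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.170 with an estimated correlation). 7SL RNAs went the other way, as 8 of 63 rose (8 adjusted over the list alone, camera adjusted p = 7.1e-13), with RN7SL3 at 13.7 against 15.8 CPM (log2 2.63, -0.20 with library totals). hsa-miR-92a-3p (11162 against 25403 CPM, log2 fold change 1.35, adjusted p = 0.177) did not pass. With FPLC 633 of 7009 features passed, 164 higher and 469 lower, and with library totals 4051 passed, 19 higher and 4032 lower, with a median of -1.80 (-4.12 with library totals). Without FPLC supermere C or D, 415 and 411 passed. RN7SL3 lost its call without any 1 library but exomere A or supermere D (log2 2.35 to 2.61), and the 7SL median turned to -0.66 with library totals. Without exomere A VTRNA1-1 had -5.37, and without exomere B hsa-miR-21-5p -2.33 and hsa-miR-200c-3p -5.02.

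By the test FPLC exomere held more snoRNA, VTRNA1-1 and hsa-miR-21-5p and less RNY1 and RNY4 than UC exomere, though 3 of 35 groupings of the libraries called at least as many features as the real one (680, highest 1173), so the count is not set apart from chance. SNORD3A rose to 3504 against 32.6 CPM (n = 4 and 3, log2 5.41) and VTRNA1-1 to 53196 ± 39030.4 against 3595 ± 2610.2 CPM (SD, n = 4 and 3, log2 fold change 2.73, SE 0.84, adjusted p = 0.0248). hsa-miR-21-5p was at 26468 ± 26244 against 1612 ± 968 CPM (log2 fold change 2.63, SE 0.76, adjusted p = 0.0147) and hsa-miR-200c-3p at 4829 ± 4089 against 277 ± 69.3 CPM (log2 2.76). RNY4 fell to 26188 ± 3644 against 126508 ± 14299 CPM (log2 -3.49), RNY1 to 69332 ± 9923 against 198685 ± 47722 CPM (log2 -2.75) and hsa-miR-484 to 579 ± 571 against 2773 ± 733 CPM (log2 -3.62). RN7SKP187, a copy of 7SK, and SNHG20, a snoRNA host transcript, had 0 counts in UC exomere and were at least 1444-fold and at least 1656-fold higher. Of the C/D box snoRNAs 55 of 152 rose and 1 fell (71 and 5 adjusted over the list alone, camera adjusted p = 2.7e-11, adjusted p = 0.197 with an estimated correlation). In the H/ACA box list 26 of 89 rose and 0 fell (46 and 1 adjusted over the list alone, camera adjusted p = 2.4e-10, adjusted p = 0.144 with an estimated correlation). Y RNAs split, as 82 of 277 rose and 43 fell (113 and 60 adjusted over the list alone, camera adjusted p = 0.137). Of the 7SL RNAs 8 of 63 fell (9 adjusted over the list alone, camera adjusted p = 2.7e-11). Between the methods 659 of 7009 features passed, 437 higher and 222 lower, and with library totals 1173 passed, 1087 higher and 86 lower, with a median of 0.67 (2.05 with library totals). Without 3D UC exomere A, B or C, 382, 227 and 244 passed, and without FPLC exomere B, in which hsa-miR-21-5p reached 65574 CPM, 400. Calls were lost for VTRNA1-1 without any 1 UC library or FPLC exomere A, B or D, for hsa-miR-21-5p without UC B or C or FPLC B (1.89 to 2.89), for hsa-miR-200c-3p without any 1 UC library or FPLC B (2.15 to 2.96) and for RNY1 without UC B (-2.28).

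Between the methods supermeres differed in few features, 28S rRNA and VTRNA1-1 among them. 28S rRNA, of the large ribosomal subunit, was at 567234 ± 350728 against 4770.4 ± 1479 CPM (SD, n = 4 and 2) in FPLC against UC (log2 fold change 9.08, SE 0.97, adjusted p = 4.0e-17). VTRNA1-1 rose to 112 ± 56.5 against 3.02 ± 3.93 CPM (log2 fold change 6.86, SE 1.27, adjusted p = 3.1e-04) and RN7SKP187 to 79.2 ± 68.6 against 0.363 ± 0.513 CPM (log2 7.96), and mt-tRNA18-TS2 fell to 8.39 ± 6.88 against 883 ± 9.44 CPM (log2 -5.20). In the vault RNAs 3 of 4 rose (4 adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.0730 with an estimated correlation). For 7SK RNA 4 of 22 rose and 0 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0689). In the Y RNAs 1 of 277 rose and 6 fell (3 and 16 adjusted over the list alone, camera adjusted p = 0.0745). RNY1 was at 92838 against 486388 CPM (log2 fold change -0.78, adjusted p = 0.704), RNY4 at 26946 against 81115 CPM (log2 fold change 0.15, adjusted p = 1), hsa-miR-92a-3p at 11162 against 4753 CPM (log2 fold change 2.67, adjusted p = 0.119) and hsa-miR-200c-3p at 16.8 against 4.95 CPM (log2 fold change 2.93, adjusted p = 0.263), none of which passed. Here 16 of 7009 features passed, 9 higher and 7 lower, and with library totals 39 passed, 5 higher and 34 lower. Without 3D UC supermere C 3 features passed and without FPLC supermere D 10. VTRNA1-1 lost its call without UC supermere C (log2 5.99) and RN7SKP187 without UC supermere B (6.89), and 28S rRNA had 7.69 without FPLC supermere A.

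Along the gradient, pool 9_10 had higher VTRNA1-1 and lower let-7 miRNAs than pool 6_7 by TMM. VTRNA1-1 rose to 34314 ± 56333 against 429.9 ± 153 CPM (SD, n = 4 and 4, log2 fold change 4.31, SE 0.81, adjusted p = 8.0e-05), with 118056 CPM in replicate D and 302 to 17011 in the others; without D the mean was 6400 CPM and the log2 2.25. MER39, an endogenous retrovirus family, had 0 counts in 6_7 and was at least 209-fold higher. RN7SL1 fell to 46.9 ± 22.0 against 189 ± 66.6 CPM (log2 fold change -4.89, SE 0.96, adjusted p = 9.4e-05), hsa-let-7a-5p to 5749 ± 1534 against 15082 ± 6283 CPM (log2 -3.95) and hsa-miR-423-5p to 149 ± 101 against 766 ± 307 CPM (log2 -4.72). hsa-miR-21-5p passed with a log2 of -2.48 by TMM although its CPM were 73246 ± 19942 against 61673 ± 22477 CPM, and its log2 was 0.26 with library totals. NORAD, a lncRNA that binds PUMILIO proteins, fell to 11.9 ± 10.1 against 70.1 ± 21.9 CPM (log2 -5.33). Of the let-7 family 9 of 9 fell (9 adjusted over the list alone, camera adjusted p = 3.0e-16); within miRNA alone 4 of these 9 fell, and over all miRNAs 14 passed, 4 higher and 10 lower, so most of the miRNA fall by TMM was absent there. Of the 7SL RNAs 3 of 63 rose and 21 fell (5 and 34 adjusted over the list alone, camera adjusted p = 2.2e-20). Of the vault RNAs 3 of 4 rose (3 adjusted over the list alone, camera adjusted p = 0.997). In the Y RNA list 1 of 277 rose and 102 fell (2 and 124 adjusted over the list alone, camera adjusted p = 4.7e-52), while the Y RNA share of counts was 11.2% ± 5.96 against 3.62% ± 1.42 (SD). RNY1 was at 25532 against 4938 CPM (log2 fold change -0.12, adjusted p = 1). Between these pools 983 of 7009 features passed, 498 higher and 485 lower, and with library totals 3575 passed, 3560 higher and 15 lower; the median was 3.35 (5.89 with library totals), and the medians of the miR-200, miR-17-92, snoRNA, nuclear tRNA and rRNA lists changed sign with library totals. Without 9_10 A or D, 446 and 1885 passed, and without 6_7 A, C or D 652, 622 and 424. Without 9_10 B hsa-miR-21-5p lost its call (log2 -1.40), and RN7SL1 had -3.79, hsa-let-7a-5p -2.79, hsa-miR-423-5p -3.48 and NORAD -3.81.

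Pool 12 fell below pool 6_7 in let-7 miRNAs, tRNA and Y RNA features and rose in snRNA and snoRNA. hsa-let-7a-5p fell to 92.9 ± 51.3 against 15082 ± 6283 CPM (SD, n = 4 and 4) in 12 against 6_7 (log2 fold change -6.68, SE 0.87, adjusted p = 8.6e-12), hsa-miR-21-5p to 704 ± 428 against 61673 ± 22477 CPM (log2 fold change -5.84, SE 0.79, adjusted p = 5.7e-11) and hsa-miR-200c-3p to 127 ± 77.9 against 13449 ± 4378 CPM (log2 -6.09). tRNA-Ile-GAT fell to 5.82 ± 3.72 against 2347 ± 693 CPM (log2 -8.24), tRNA-Gly-GCC to 355 against 94576 CPM (log2 -7.38) and RNY1 to 149.8 ± 105 against 4938 ± 2063 CPM (log2 -4.34). RNU12 rose to 41122 against 335 CPM (log2 7.14), RN7SK to 773 against 37.2 CPM (log2 4.92), SNORD14A, a C/D box snoRNA, to 408 ± 531 against 3.44 ± 4.20 CPM (log2 7.32) and VTRNA1-1 to 4452 ± 2687 against 429.9 ± 153 CPM (log2 fold change 4.03, SE 0.80, adjusted p = 2.1e-05). hsa-miR-1246, an entry that overlaps U2 snRNA, was at 360490 ± 102460 against 36645 ± 24772 CPM and did not pass (log2 fold change 3.54, adjusted p = 0.0686). Of the let-7 family 9 of 9 fell (9 adjusted over the list alone, camera adjusted p = 1.2e-23). Of the miR-17-92 cluster and paralogs 12 of 12 fell (12 adjusted over the list alone, camera adjusted p = 1.7e-18). Of the 5′-half tRNAs 9 of 9 fell (9 adjusted over the list alone, camera adjusted p = 1.0e-17). In the spliceosomal list 62 of 259 rose and 3 fell (72 and 6 adjusted over the list alone, camera adjusted p = 7.6e-23). For 7SK RNA 9 of 22 rose and 0 fell (9 and 1 adjusted over the list alone, camera adjusted p = 1.1e-07) and for 7SL RNA 1 of 63 rose and 26 fell (3 and 36 adjusted over the list alone, camera adjusted p = 6.3e-20). Of the H/ACA box snoRNAs 25 of 89 rose and 0 fell (36 and 2 adjusted over the list alone, camera adjusted p = 2.7e-09), and vault RNAs 3 of 4 rose (4 adjusted over the list alone, camera adjusted p = 9.3e-04, adjusted p = 0.105 with an estimated correlation). Of the blood cell miRNAs 5 of 7 fell (5 adjusted over the list alone, camera adjusted p = 5.0e-07), with hsa-miR-142-5p at 6.97 against 433 CPM (log2 -5.37). In all 696 of 7009 features passed, 204 higher and 492 lower, and with library totals 603 passed, 111 higher and 492 lower. The strict filter gave 533 higher and 390 lower, and RLE factors without the near-empty library 933 and 257. Within miRNA alone 53 rose and 65 fell, and hsa-miR-92a-3p, here at 883 ± 644 against 22672 ± 10755 CPM (log2 -4.00), had a log2 of 0.06, and hsa-miR-210-3p, at 3.49 against 56.0 CPM (log2 -3.35), one of 0.74. Without 12 A RNU12 had 6.42, and without 12 B SNORD14A 6.15.

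Pool 12 held more snRNA and snoRNA than pool 9_10 by TMM. RN7SK rose to 773 against 18.6 CPM (n = 4 and 4, log2 8.95) and SNORA14B, an H/ACA box snoRNA, to 128 ± 94.3 against 1.35 ± 2.69 CPM (SD, n = 4 and 4, log2 fold change 9.97, SE 1.40, adjusted p = 1.4e-09). hsa-miR-1246 rose to 360490 ± 102460 against 80134 ± 108739 CPM (log2 fold change 5.67, SE 1.36, adjusted p = 0.00685), the 9_10 mean being 25906 without A. hsa-miR-21-5p fell to 704 ± 428 against 73246 ± 19942 CPM (log2 fold change -3.35, SE 0.70, adjusted p = 9.1e-05), RNY1 to 149.8 ± 105 against 25532 ± 14329.8 CPM (log2 -4.22) and hsa-miR-200c-3p to 127 ± 77.9 against 11326 ± 3569 CPM (log2 -3.26). Of the spliceosomal snRNAs 120 of 259 rose and 11 fell (170 and 12 adjusted over the list alone, camera adjusted p = 1.8e-96). Of the H/ACA box snoRNAs 30 of 89 rose (41 adjusted over the list alone, camera adjusted p = 1.8e-30). Of the C/D box snoRNAs 33 of 152 rose and 0 fell (51 and 2 adjusted over the list alone, camera adjusted p = 7.0e-25), and their median was above 0 with TMM and below 0 with library totals. For the let-7 family 8 of 9 fell (8 adjusted over the list alone, camera adjusted p = 1.9e-08, adjusted p = 0.0784 with an estimated correlation). VTRNA1-1 was at 4452 against 34314 CPM (log2 fold change -0.28, adjusted p = 0.888). Here too 433 of 7009 features passed, 236 higher and 197 lower, and with library totals 3871 passed, 60 higher and 3811 lower, with a median of -2.09 (-5.41 with library totals). Without 9_10 A SNORA14B had a log2 of 8.85, and without 9_10 D RNY1 -3.23 and hsa-miR-200c-3p -2.45.

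Pool 6_7 and UC sEV, both from 3D medium, differed in vault RNA, snRNA and snoRNA. VTRNA1-1 was at 429.9 ± 153 against 46160 ± 18189.6 CPM (SD, n = 4 and 3) in pool 6_7 against sEV (log2 fold change -6.76, SE 0.92, adjusted p = 1.5e-09), RNY1 at 4938 ± 2063 against 91047 ± 8434 CPM (log2 fold change -4.29, SE 0.72, adjusted p = 6.4e-07) and SNORD3D ENSG00000277947.1, a C/D box snoRNA, at 7.24 ± 3.15 against 1318 ± 625 CPM (log2 -7.60). tRNA-Glu-CTC rose to 56282 ± 24869.5 against 2837 ± 2090.3 CPM (log2 fold change 4.27, SE 0.86, adjusted p = 6.1e-05) and EPCAM-DT, a transcript divergent from the epithelial marker gene EPCAM, to 2408 ± 982 against 175 ± 74.4 CPM (log2 3.74). hsa-miR-21-5p (61673 against 46967 CPM, log2 fold change 0.33, adjusted p = 0.835), hsa-let-7a-5p (15082 against 7272 CPM, log2 fold change 0.95, adjusted p = 0.398) and hsa-miR-200c-3p (13449 against 5692 CPM, log2 fold change 1.19, adjusted p = 0.287) did not pass. Of the spliceosomal snRNAs 2 of 259 rose and 101 fell (7 and 132 adjusted over the list alone, camera adjusted p = 3.5e-24, adjusted p = 0.0522 with an estimated correlation). Of the vault RNAs 4 of 4 fell (4 adjusted over the list alone, camera adjusted p = 1.1e-04, adjusted p = 0.119 with an estimated correlation). For C/D box snoRNAs 60 of 152 fell (89 adjusted over the list alone, camera adjusted p = 9.4e-21). Of the mitochondrial tRNAs 14 of 21 fell (19 adjusted over the list alone, camera adjusted p = 5.2e-09, adjusted p = 0.0522 with an estimated correlation). In the let-7 family 0 of 9 fell (0 adjusted over the list alone, camera adjusted p = 2.6e-05, adjusted p = 0.234 with an estimated correlation). Of the 7SL RNAs 3 of 63 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 7.5e-17). Here 540 of 7009 features passed, 23 higher and 517 lower, and with library totals 370 passed, 18 higher and 352 lower, with a median of -3.05 (-2.42 with library totals). Without 3D UC sEV B 265 passed, and without 6_7 A, C or D 307, 287 and 272. With RLE scaling 62 were higher and 49 lower, and with the 2 groups alone 245 and 473.

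**Figure D3:**
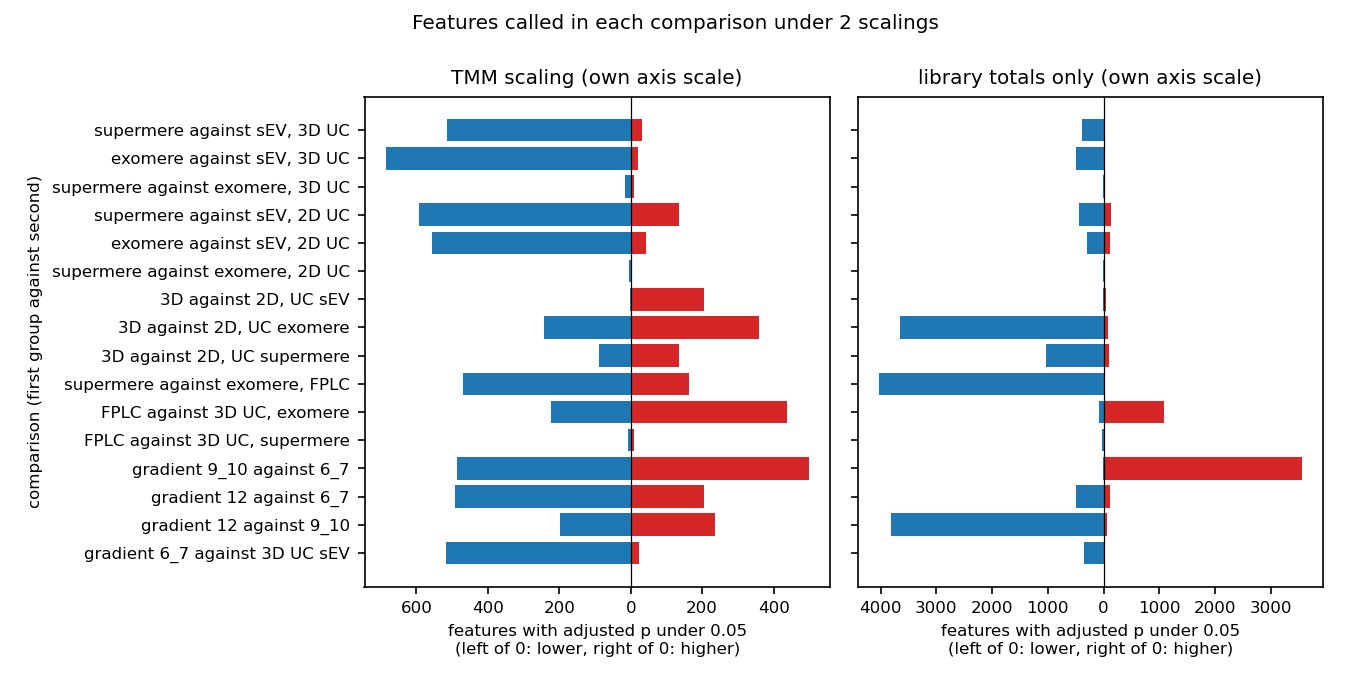
Number of features called higher (right of 0) and lower (left of 0) in each of the 16 comparisons, with TMM scaling in one panel and library totals in the other, each on its own axis scale. The split between higher and lower turns with the scaling in the comparison of gradient 12 with 9_10, from 236 higher and 197 lower to 60 and 3811.

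Some RNAs were called for a change with culture in the difference between supermere and sEV, but 3 of 40 groupings called at least as many (115, highest 168), so the count is not set apart from chance. hsa-miR-21-5p was lower in supermere relative to sEV in 3D than in 2D (log2 difference -5.57, SE 1.14, adjusted p = 2.1e-04), with a log2 of -6.07 in 3D and -0.50 (adjusted p = 1) in 2D, and RNY4 was higher in supermere relative to sEV in 3D than in 2D (log2 difference 6.15, SE 1.12, adjusted p = 2.2e-05). RNU2-64P, a U2 pseudogene, had a log2 difference -12.27, SE 1.72, adjusted p = 4.9e-09. Of the Y RNAs 30 of 277 rose and 0 fell (53 and 9 adjusted over the list alone, camera adjusted p = 2.1e-45, adjusted p = 0.138 with an estimated correlation). Of the spliceosomal snRNAs 39 of 259 fell (75 adjusted over the list alone, camera adjusted p = 5.3e-17, adjusted p = 0.233 with an estimated correlation). Over all features 116 of 7009 features passed, 37 higher and 79 lower, and with library totals 103 passed, 19 higher and 84 lower, with a median of -3.08 (-3.58 with library totals). Without 2D UC sEV A 77 passed and without 3D UC supermere C 49. Without 2D UC supermere C RNU2-64P had -7.19 and hsa-miR-21-5p -4.72, and without 3D UC supermere C RNY4 had 5.00. The balance turned with RLE factors without the near-empty library (89 higher, 51 lower), DESeq2 (241, 87) and the strict filter (76, 59).

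Between the methods the difference of supermere from exomere was called for 28S rRNA and some small RNAs, but 3 of 40 groupings called at least as many (146, highest 242), so the count is not set apart from chance. 28S rRNA had a log2 difference 5.98, SE 0.99, adjusted p = 4.7e-06 for FPLC minus UC by TMM, and 1.13 with an adjusted p = 0.911 by library totals. hsa-miR-484 had a log2 difference 5.17, SE 1.19, adjusted p = 0.00662 (2.31, adjusted p = 0.196 by library totals), hsa-miR-92a-3p a log2 difference 4.32, SE 1.04, adjusted p = 0.0110 (1.67, adjusted p = 0.381) and SNORD26, a C/D box snoRNA, a log2 difference -6.22, SE 1.34, adjusted p = 0.00227. For 7SL RNA 6 of 63 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 1.3e-17), and for vault RNAs 0 of 4 rose (4 adjusted over the list alone, camera adjusted p = 0.00371, adjusted p = 0.426 with an estimated correlation). Over all features 138 of 7009 features passed, 59 higher and 79 lower, and with library totals 472 passed, 3 higher and 469 lower, with a median of 0.00 (-2.14 with library totals). Leaving out 1 library of 3D UC exomere B or C, 3D UC supermere A, B or C or FPLC supermere A, B, C or D left 79, 73, 45, 55, 34, 84, 47, 73 and 73. hsa-miR-92a-3p lost its call without 3D UC supermere A (3.79) and SNORD26 without 3D UC supermere B (-4.90), and 28S rRNA had 4.59 without FPLC supermere A.

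Fraction effects (log2) were compared between cultures and methods across features, which are not independent. Supermere against sEV in 3D and 2D had r = 0.363, rho = 0.227 and the same sign in 379 of 384 called in both (378 lower). Exomere against sEV had r = 0.331, rho = 0.245 and 374 of 385 (372 lower). Supermere against exomere had r = 0.0447 between 3D and 2D, with 3 of 3, all vault RNAs, and r = 0.0639 between FPLC and 3D UC, with 17 of 20 (17 lower). Gradient 12 against 6_7 and 3D UC exomere against sEV had r = 0.161 and 282 of 342 (282 lower). Most calls were lower, favouring a same sign.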

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

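The tests of explanations for single patterns below were chosen after the result was seen, while the comparison of other groupings of the libraries was set before.

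VTRNA1-1 was lower in supermere than in exomere in 2D UC, 3D UC and FPLC, the only feature group to do so in all 3 settings by the test. With rRNA and Y RNA left out the highest of the 3 ratios of shares was 0.0166, so their reads do not account for it. Other abundant RNAs, the larger part in 2D UC, were not left out. Reads moved between vault RNA copies would leave the sum over all copies alike, and its highest ratio was 0.0117. A shallow library could miss it, but at the exomere share the supermere library with the lowest expectation would hold 1536.02 counts and held 8. VTRNA1-1 was in turn lower in exomere than in sEV in both UC cultures, so it was not particular to exomeres. Beyond these counting explanations no cause was tested. That vault RNA is lost before the supermere spin or column fraction is a hypothesis, which vault protein measured in all fractions could test.

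hsa-miR-1246 took a larger share of counts in gradient 12 than in 6_7, although it missed the threshold by TMM. Its entry overlaps U2 snRNA, and if U2 reads were counted in proportion the ratio of hsa-miR-1246 to all U2 counts would be alike, but it was 2.58 times as high in 12 (exact permutation test, two-sided, p = 0.0286, the lowest that 4 against 4 allows). Its share of counts other than 28S rRNA was 11.2 times as high, but this decides nothing, as 6_7 mostly held less 28S rRNA. A U2 fragment kept in that pool may be the cause, and reads mapped along U2 would show whether they end at the miRNA entry.

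Y RNA took a larger share in 3D UC exomere and supermere than in the FPLC preparations. For exomere, rRNA in the FPLC libraries cannot account for it: the highest FPLC share of counts other than rRNA was 41.8%, and the lowest of UC 68.2%. For supermere, FPLC A and B had 86.8 and 81.7% of counts other than rRNA, within the range of UC (80.8 to 94.3%), so rRNA reads could lower it there; C had 76.0%, and D, with 7.67% rRNA, 31.3%, which rRNA does not account for, though 1 library does not exclude it for the group. Whether Y RNA particles pellet in UC and leave the exomere fraction on the column could be tested by measuring RNY1 across all column fractions.

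Groupings were fitted with the dispersion trend held, so real counts differ slightly from those in the report. The gradient comparisons and the FPLC comparison called more features with the real grouping than with any of the other 34: 1000 against at most 39 for 9_10 with 6_7, 716 against 3 for 12 with 6_7, 445 against 23 for 12 with 9_10, 540 against 310 for 6_7 with sEV, 639 against 293 for FPLC supermere with exomere and 16 against 4 for FPLC with 3D UC supermere. Only the real grouping, 1 of 35, reached its count, the lowest share possible and unadjusted over comparisons. For FPLC with 3D UC exomere 3 of 35 groupings reached the real count of 680, the highest calling 1173, so chance cannot be excluded, and that grouping sets 3D UC exomere A with FPLC exomere B, C and D. For the differences between cultures and between methods 3 of 40 groupings each reached the real counts of 115 and 146, with up to 168 and 242, and chance cannot be excluded. In UC, 10 groupings per comparison are too few for a share under 0.05. There 1 of 10, the real one, called the most for supermere with sEV (550 against 18 in 3D, 726 against 8 in 2D), exomere with sEV (720 against 16, 615 against 0), and 3D with 2D (209 against 22 for sEV, 613 against 8 for exomere, 225 against 147 for supermere). For supermere with exomere 3 of 10 groupings in 3D and 5 of 10 in 2D called as many as the real ones (27 and 7), and the highest called 212 and 79, several times the real count, which points to a structure among the samples. In 3D the 212 came from setting the near-empty supermere A with exomere A and B. In 2D, where 1 library correlated best with its own letter, the 4 groupings with 45 to 79 all set exomere C with supermere C. The 3 others that part every letter called 0. For 3D with 2D exomere the others that part every letter called at most 3.

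In groups of 4, 20 of 121 values had a library outside the spread of the others. Chance flags about 1 in 20 groups of independent normal values, which these are not. With 0 in others (hsa-miR-451a) any count is flagged. FPLC exomere A had 20.6% tRNA (others 0.958 to 3.82%), and B hsa-miR-21-5p at 65574 CPM (9238 to 16156), hsa-miR-200c-3p at 10899 (2287 to 3621), hsa-miR-100-5p at 7.07 (0.266 to 0.430) and hsa-miR-451a at 8.25. FPLC supermere D had 22.8% miRNA (0.901 to 3.89%), 39.3% snRNA (0.162 to 4.01%), hsa-miR-1246 at 153472 CPM (515 to 7164) and hsa-miR-210-3p at 119 (15.5 to 29.4). Supermere A had 8.14% Y RNA (26.6 to 29.4%), and C hsa-miR-451a at 0.276 CPM. Gradient 6_7 B had 1.52% Y RNA (4.04 to 4.55%), 1.41% snRNA (0.530 to 0.646%), 0.523% lncRNA (1.24 to 1.39%) and 0.101% miscellaneous RNA (0.217 to 0.228%). Gradient 9_10 A had hsa-miR-1246 at 242819 CPM (16628 to 35784), and D VTRNA1-1 at 118056 (302 to 17011) and hsa-miR-451a at 5.39. Gradient 12 A had 1.08% tRNA (0.246 to 0.378%), and B 0.01002% endogenous retrovirus RNA (0.0621 to 0.0636%).

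The effect of fraction differed between cultures for 116 features, among them hsa-miR-454-3p (log2 difference 8.55, adjusted p = 5.2e-04), SNORD22 ENSG00000277194.1 (-15.84, 1.1e-06, with 0 counts in 3D supermere), hsa-miR-21-5p (-5.57, 2.1e-04), RNY4 (6.15, 2.2e-05) and RNU2-64P (-12.27, 4.9e-09). Between methods it differed for 138 features, among them 28S rRNA (5.98, 4.7e-06), hsa-miR-484 (5.17, 0.00662), hsa-miR-92a-3p (4.32, 0.0110), RNY4 (3.64, 0.0280), SNHG20 (-12.80, 9.9e-07) and SNORD26 (-6.22, 0.00227). With library totals calls were lost for hsa-miR-454-3p (7.65, 0.0502), 28S rRNA (1.13, 0.911), hsa-miR-484 (2.31, 0.196), hsa-miR-92a-3p (1.67, 0.381) and RNY4 between methods (0.84, 1), the last 2 also without the near-empty library (3.79, 0.0621 and 2.97, 0.145).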

How the results depend on the processing

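The settings were fixed before the data were examined, except for leaving out the near-empty library and summing copies of a family. Counts are features that passed, and why a setting moved a count was not tested. Of 296 pairs of a feature and a comparison that passed, which include all those named in the text, 170 kept their call under every setting run for single features (not family sums, nor RLE or library totals without the near-empty library, and miRNA alone for 110 pairs), 117 lost it under at least 1 and 9 changed direction. RLE factors rest on 11 features counted in all 38 libraries and on 253 without the near-empty library, so counts with RLE in all libraries are weak, and counts with library totals follow the abundant RNAs. Without the near-empty library the filter kept 8979 features, so calls lost without a library may reflect the tested set.

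With RLE scaling the counts were 421 for exomere against sEV in 3D, 365 in 2D, 90 for supermere against exomere in 3D, 3 in 2D, 36, 4403 and 5724 for 3D against 2D sEV, exomere and supermere, 3765 for FPLC supermere against exomere, 2820 for gradient 9_10 against 6_7, 111 for 6_7 against sEV, 2207 for the difference between cultures and 66 for that between methods. With library totals they were 58, 3725 and 1131 for 3D against 2D sEV, exomere and supermere, 4051 for FPLC supermere against exomere, 1173 and 39 for FPLC against UC exomere and supermere, 3575 for 9_10 against 6_7, 3871 for 12 against 9_10 and 472 for the difference between methods. RLE without the near-empty library gave 296, 286 and 58 for supermere against sEV, exomere against sEV and supermere against exomere in 3D, 3 for the last in 2D, 96 and 2129 for 3D against 2D sEV and exomere, 39 for FPLC against UC supermere, 3344 for 9_10 against 6_7, 1190 for 12 against 6_7 and 228 for 6_7 against sEV.

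With no filter they were 281, 375 and 15 for supermere against sEV, exomere against sEV and supermere against exomere in 3D, 92, 114 and 145 for 3D against 2D sEV, exomere and supermere, 290 for FPLC supermere against exomere, 157 for FPLC against UC exomere, 990 for 6_7 against sEV, and 76 and 29 for the differences between cultures and methods. The strict filter gave 1496 for 9_10 against 6_7.

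With the compared groups alone 15 passed for supermere against exomere in 3D and 28 in 2D, 763, 1480 and 694 for 3D against 2D sEV, exomere and supermere, 233 and 74 for FPLC against UC exomere and supermere, 324 for 9_10 against 6_7, and 215 and 67 for the differences between cultures and methods. With DESeq2 they were 333 for supermere against sEV in 3D, 375 and 31 for supermere against exomere in 3D and 2D, 354 and 654 for 3D against 2D exomere and supermere, 359 and 254 for FPLC against UC exomere and supermere, and 328 and 742 for the differences. With the letter as a block 359 and 9 passed for FPLC against UC exomere and supermere and 64 for the difference between methods, and without the near-empty library 45 for the latter.

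With copies of a family summed they were 262 and 364 for supermere against sEV in 3D and 2D, 410 and 329 for exomere against sEV, 67, 219 and 68 for 3D against 2D sEV, exomere and supermere, 271 for FPLC supermere against exomere, 252 and 6 for FPLC against UC exomere and supermere, 614, 378 and 154 for 9_10 against 6_7, 12 against 6_7 and 12 against 9_10, 327 for 6_7 against sEV, and 22 and 78 for the differences.

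Leaving out each library in turn gave, in 3D, 164 to 462 for supermere against sEV, 413 to 538 for exomere against sEV and 8 to 28 for supermere against exomere, and in 2D 545 to 664, 375 to 503 and 0 to 29. It gave 70 to 170, 194 to 472 and 72 to 189 for 3D against 2D sEV, exomere and supermere, 411 to 615 for FPLC supermere against exomere, 227 to 805 and 3 to 19 for FPLC against UC exomere and supermere, 424 to 1885 for 9_10 against 6_7, 561 to 704 for 12 against 6_7, 301 to 384 for 12 against 9_10, 265 to 474 for 6_7 against sEV, and 49 to 129 and 34 to 202 for the differences between cultures and methods. Of 60 tests of class shares 29 passed, and 23 to 31 with a library left out. With rRNA left out of the denominator 19 of 54 tests passed in both, and with the most abundant feature left out 24 of 60.

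Camera called 253 of 378 pairs of list and comparison, 95 with an estimated correlation and 248 with the letter as a block. For miRNA lists it called 109 of 162, and 52 within miRNA alone. The r of log2 fold changes within miRNA alone was 0.612 for supermere against sEV in 3D and 2D, 0.514 for exomere against sEV (0.490 with the strict filter), 0.167 for supermere against exomere in FPLC and 3D UC, and 0.324 for gradient 12 against 6_7 with exomere against sEV. With a library left out r ran from 0.301 to 0.342, 0.277 to 0.313, -0.00452 to 0.0477 (supermere against exomere in 3D and 2D), 0.0515 to 0.0776 and 0.121 to 0.163.

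In 3D against 2D exomere SCARNA10 had a log2 of -4.87, which ran from -6.45 to 0.55 as libraries were left out, the last without 2D UC exomere C. There hsa-let-7a-5p had 2.45, -1.37 with RLE and -0.44 with library totals, and hsa-miR-200c-3p 2.93 and -0.69 with RLE. In 3D against 2D supermere hsa-miR-150-3p was lower with edgeR and had 1.89 with DESeq2, and hsa-miR-125b-5p had 4.38 and -1.80 with RLE. In gradient 9_10 against 6_7 hsa-miR-21-5p had -2.48, 0.26 with library totals and 0.13 within miRNA. In 12 against 6_7 hsa-miR-92a-3p had -4.00 and 0.062 within miRNA, and hsa-miR-210-3p -3.35 and 0.74. In FPLC supermere against exomere RN7SL3 had 2.63, -0.30 with RLE and -0.20 with library totals.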

Other observations

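The tests here were set before the data were examined, while the choice of what to describe was made after the result was seen. Of the miRNA entries that overlap other structured RNAs, in gradient 12 against 9_10 3 of 13 rose (3 adjusted over the list alone, camera adjusted p = 0.00192, adjusted p = 0.0925 with an estimated correlation), and hsa-miR-1290, which overlaps snRNA sequence, also rose in 12 against 6_7 (52.9 against 1.84 CPM, log2 5.23) and in exomere against sEV in 2D (41.2 against 1.86 CPM, log2 3.56), where it lost its call without 2D UC exomere C, which held 97.1 CPM (log2 0.85 without). Intestinal epithelial miRNAs fell in pool 12: in 12 against 6_7 6 of 7 fell (6 adjusted over the list alone, camera adjusted p = 1.5e-12), with hsa-miR-194-5p at 225 against 20909.7 CPM (log2 -5.92). The miR-10, miR-99 and miR-125 miRNAs fell there as well, as 6 of 7 fell (6 adjusted over the list alone, camera adjusted p = 1.3e-11). Colorectal oncomiRs had in the same pools hsa-miR-182-5p at 53.2 against 9186 CPM (log2 -6.81), and 11 of 12 fell (11 adjusted over the list alone, camera adjusted p = 3.3e-22).

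Of the scaRNAs of Cajal bodies, which guide modification of snRNAs, 3 of 4 were tested, and in exomere against sEV in 3D 2 of 3 fell (3 adjusted over the list alone, camera adjusted p = 0.0834). Of the mesenchymal and muscle miRNAs 2 of 8 were tested.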
